A study of Spodoptera frugiperda with 12 samples.

How the data were processed

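The series covers 12 samples of *Spodoptera frugiperda* embryos in 4 groups of 3, m6A capture and input at 2 h and at 24 h after oviposition. Per the labels' protocols, embryos were frozen, total RNA was extracted with Trizol, messenger RNA was enriched on oligo(dT) beads and cut to short fragments, and these were split into an m6A antibody capture and an uncaptured input. Libraries were made with random primers and an NEBNext Ultra RNA kit and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The protocol does not describe the kit as marking strand. The 6 input samples have no peak list of their own and were not analysed here, so a locus without a peak can be a locus without detectable RNA.

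Per the submitters' processing notes, fastp 0.20.0, Bowtie2 2.2.5, HISAT2 2.1.0 and HOMER were used. The notes give no roles, and the peak caller, its threshold, the genome build and the annotation are not given in the sources used here. The deposited lists hold 6 columns (sequence, start, end, name, score and strand) and were made per sample, without pooling. The score is the authors' own value per peak, and its scale is not stated in the deposited lists. It was used only to rank and describe peaks within a list. From 0.930% to 1.50% of peaks per list had an infinite score. Of the peaks that span at most 200 bases, about 96.2% to 96.4% per list are a whole multiple of 25 bases long, while of those above 1000 bases 3.58% to 4.39% are, close to the 4% of chance. Long spans thus did not follow the 25-base steps of the short ones, and they were read as genomic extents that can include introns, not as lengths of transcript. Of the peaks that span at most 1000 bases, fewer than 1% in each list overlapped a peak of the opposite strand in the same list. Longer spans were not counted in this share.

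No genome or annotation of the sequences in the lists was used here. The RefSeq gene table at hand belongs to assembly GCF_023101765.2 (AGI-APGP_CSIRO_Sfru_2.0), whose chromosomes are not those of the lists, so nuclear genes were not named. The planned position in transcripts, DRACH motif share, nuclear stage-exclusive genes and 17 gene lists were not analysed here. The mitochondrial sequence is an exception: 161 of 180 mitochondrial peaks (89.4%, against 4% by chance) started a whole number of 25-base steps from the start of a coding gene they began in, and all 180 overlapped a coding gene, so the 13 mitochondrial coding genes were matched by position.

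From the lists, the number of peaks, the strand-aware union length and the median span were computed per list. The base-pair Jaccard index was computed for all 15 pairs. Peaks of all 6 lists were merged on 1 strand when they overlapped by at least 1 base, and this gave 114500 regions, the same number as with bedtools merge 2.31.1. Loci were made by joining peaks of 1 strand less than 2000 bases apart, a choice made after the data were seen. A region or locus was exclusive to a time when it had a peak in 3 of 3 lists of that time and 0 of 3 of the other. In simulated lists of 2400 loci with 200 exclusive to each time and scattered background peaks, 89.0% of the 2 h-only and 89.5% of the 24 h-only loci were recovered, with 0 false ones. Shared loci had their peaks in all 6 simulated lists, so the 0 says nothing about false exclusive loci from missed peaks. Position along a locus used peak midpoints of peaks that span at most 1000 bases.

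Values per list were compared with two-sided exact permutation tests of 3 against 3, whose smallest p is 0.1. The excess of within-time over between-time overlap was tested one-sided over the 10 splits of the 6 lists. Differences between parts of loci were tested with two-sided exact sign-flip tests over 6 lists (smallest p 0.03125). Benjamini-Hochberg adjustment was made over the 13 mitochondrial genes and over the 3 position comparisons. Regions were named by a rule fixed before the data were examined: the 5 exclusive regions per time with the highest smallest within-list score percentile of the strongest peak. Loci were named as the 5 per time with the most peaks in their poorest list, a rule set after the data were seen.

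The alternatives fixed before the data were examined were the stronger 50% of each list by score, the strongest 51157 peaks of each list, each list left out in turn, an overlap of at least 50% of the shorter peak, presence in at least 2 of 3 lists, the share of peaks overlapped in place of the Jaccard index, a peak midpoint inside the gene, and a replicate block. Those added later were spans of at most 1000 bases, strand ignored, joining distances of 500 and 10000 bases, and lists without peaks of 75 bases, also with the share of peaks overlapped. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.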

Results

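N6-methyladenosine (m6A), a methyl mark on adenosines inside messenger RNA, was mapped in whole embryos of the fall armyworm *Spodoptera frugiperda*, a noctuid moth, at 2 h and 24 h after the eggs were laid. The design asked how the m6A profile of the embryo differs between these 2 times. RNA fragments were captured with an antibody against m6A and sequenced beside uncaptured input, and each of the 6 captured samples (3 per time) has its own deposited list of m6A peaks, the stretches called as enriched. The 6 lists held 331440 peaks in all, from 51157 to 58161 per list, with a median span of 75 bases in every list. The deposited lists give no read counts, so the depth behind a peak is unknown. Positions are given on the sequence names of the deposited lists, counted from 1, and the genome build behind them is not given in the sources used here. Nothing in the labels says that the 3 samples of a time came from separate egg batches, so p-values measure only the spread between these samples, which may be technical.

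The 24 h embryos had more called peaks than the 2 h embryos. The 2 h lists held 53231 ± 1986 peaks (SD, n = 3) and the 24 h lists 57249 ± 798 (SD, n = 3), a rise of 7.55% in the mean, and every 24 h list was longer than every 2 h list. The genomic length spanned by peaks was 23.7 ± 1.75 Mb (SD, n = 3) at 2 h and 30.3 ± 2.26 Mb (SD, n = 3) at 24 h. For the number of peaks and for the spanned length the exact two-sided permutation test gave p = 0.1, the smallest value that 3 lists against 3 can give. Both differences came from particular kinds of peak. Peaks of exactly 75 bases numbered 8505 ± 456 (SD, n = 3) at 2 h and 12623 ± 1039 (SD, n = 3) at 24 h (exact two-sided permutation p = 0.1), and without them the 24 h mean was 100 peaks lower than the 2 h mean, a difference of -100. In the stronger 50% of each list by score the excess of 75-base peaks at 24 h was 1189, against 4118 in the whole lists. Peaks of 25 bases (16196 against 16709 per list, exact two-sided permutation p = 0.4) and of 50 bases (8583 against 8756, p = 0.6) were not separated by time. Peaks that spanned over 10000 bases of genome numbered 392 ± 27.6 (SD, n = 3) at 2 h and 560 ± 47.7 (SD, n = 3) at 24 h (exact two-sided permutation p = 0.1). With peaks that spanned at most 1000 bases, the covered length was 5.85 ± 0.275 Mb (SD, n = 3) at 2 h and 5.94 ± 0.136 Mb (SD, n = 3) at 24 h, and the lists of both times overlapped in range (exact two-sided permutation p = 0.7).

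**Figure D1:**
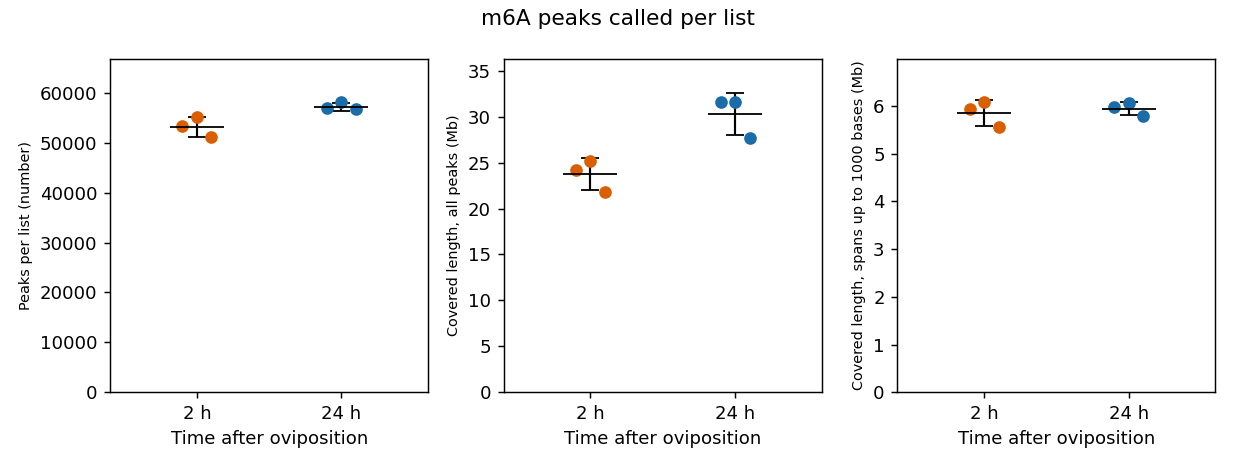
Points are the 3 peak lists of each time, the horizontal marks are means and the bars are 1 SD; the vertical axes give the number of peaks, the genomic length spanned by all peaks in Mb, and the length covered by peaks that span at most 1000 bases in Mb. The times separate in the first and second panels, and in the last panel the means are 5.85 and 5.94 Mb.

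Lists of the same time shared more of the genomic length under m6A peaks than lists of different times, mostly through the 2 h lists. The Jaccard index, the shared length divided by the joint length of 2 lists, averaged 0.531 for the 3 pairs of 2 h lists (from 0.526 to 0.542) and 0.378 for the 3 pairs of 24 h lists (from 0.372 to 0.383). Pairs of a 2 h and a 24 h list averaged 0.337 (from 0.300 to 0.362, 9 pairs). Pairs within a time exceeded pairs between times by 0.118 on average, which was the highest of the 10 splits of the 6 lists (exact one-sided p = 0.1, the smallest possible), and the next split gave -0.00014. This excess was 0.0751 to 0.0834 without 1 of the 2 h lists and 0.144 to 0.168 without 1 of the 24 h lists. Leaving out a list removes pairs of its own time, so the pairs of the other time then weigh more. With peaks that span at most 1000 bases the excess was 0.0766. Counted by peaks, as the share of peaks overlapped for at least 50% of their span, the excess was 0.0712, or 0.0655 without peaks of 75 bases. The 2 h lists overlapped each other more than the 24 h lists did, with a gap of 0.153 between the means of their pairs (exact two-sided p = 0.1 over the 10 splits). This gap was 0.158 with spans of at most 1000 bases and 0.143 by the share of all peaks overlapped. In those settings the 24 h pairs did not exceed the pairs between times on average, so the excess there came from the 2 h pairs.

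**Figure D2:**
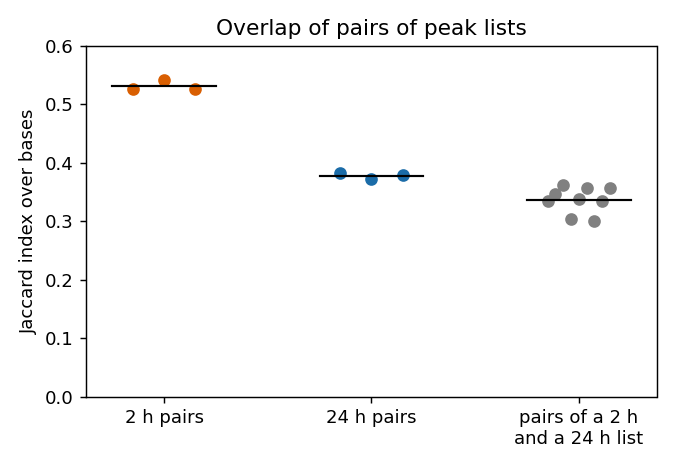
Each point is the Jaccard index over bases (vertical axis, no unit) of 1 pair of peak lists, grouped as 3 pairs of 2 h lists, 3 pairs of 24 h lists and 9 pairs of a 2 h and a 24 h list, with lines at the means. The 2 h pairs lie from 0.526 to 0.542, above all pairs of the other groups.

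Loci with m6A peaks at only 1 of the times were mostly 24 h loci. Peaks of 1 strand that lay less than 2000 bases apart were joined into 17120 loci, which stand here for transcribed units because no annotation of these sequences was used. A peak in all 6 lists was present in 8945 loci (52.2%). Peaks in all 3 of the 24 h lists and in none of the 2 h lists were present in 1252 loci, and the opposite in 96 loci, a ratio of 13.04. The contrast was smaller at equal list length (1116 against 137 loci), in the stronger 50% of each list (972 against 141) and without peaks of 75 bases (975 against 137). The 24 h-only loci held 3977 ± 63.5 peaks per 24 h list (SD, n = 3), 6.95% of a list, and the 2 h-only loci held 123 ± 7.21 peaks per 2 h list (SD, n = 3), 0.231% of a list. Of the 1252 loci present only at 24 h, 166 had at least 5 peaks in every 24 h list, and none of the 96 loci present only at 2 h had 5 in every 2 h list. In 57 of the 96 loci each 2 h list had a single peak, and in 231 of the 1252 loci each 24 h list had a single peak. For each locus the within-list score percentile of its strongest peak was taken in the list where it was lowest. The median of this value was 34.7 for 24 h-only loci, 14.6 for 2 h-only loci and 65.7 for loci of all 6 lists. The joining distance changed these counts: with 500 bases they were 1747 and 341, and with 10000 bases they were 816 and 24. A gene can be split into several loci, so a 24 h-only locus can belong to a transcript with 2 h peaks elsewhere. The counts are therefore not counts of transcripts. Leaving out any 1 of the 6 lists gave 1337 to 1708 loci at 24 h and 145 to 218 at 2 h, such as 1565 against 218 without the first 24 h list. The requirement then differed between the times, so these counts do not compare them on equal terms. Presence in at least 2 of 3 lists gave 2119 and 267.

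The 24 h-only loci with the most peaks carried large sets of m6A peaks that had no counterpart in any 2 h list. The first, on the plus strand of NC_049716.1 from 12721465 to 12739085, had 21 to 26 peaks in each 24 h list. A minus-strand locus of NC_049725.1 from 7642577 to 7647638 had 20 to 25, and a plus-strand locus of NC_049716.1 from 11514039 to 11525595 had 18 to 22. The next were a minus-strand locus of NC_049718.1 from 9449555 to 9460441 (18 to 22 peaks) and a plus-strand locus of NC_049712.1 from 16052501 to 16061343 (17 to 24 peaks). The 2 h-only loci were small. The richest lay on the plus strand of NC_049740.1 from 6634241 to 6636928 with 3 or 4 peaks per 2 h list, followed by one on the same strand from 7146141 to 7154214 with 2 to 4 and one on the plus strand of NC_049720.1 from 4722892 to 4724106 with 2 to 4. Minus-strand loci of NC_049719.1 from 11335690 to 11337003 and of NC_049722.1 from 15788753 to 15791560 had 2 peaks in every 2 h list. All 5 of these 2 h-only loci lacked a peak in every list when only the stronger 50% of each list by score was kept. The rule for naming loci was chosen after their values were seen.

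At the finer level of merged regions of overlapping peaks, both times had their own peaks. Of 114500 merged regions, 17959 (15.7%) had a peak in all 6 lists and 50954 (44.5%) had a peak in 1 list. Regions present in all 3 lists of 24 h and absent at 2 h numbered 2637, and those present at 2 h and absent at 24 h numbered 1901. The excess at 24 h was not stable: the strongest 51157 peaks of each list gave 2302 at 24 h and 2206 at 2 h, and lists without peaks of 75 bases gave 1687 at 24 h and 1857 at 2 h. The 2 sets lay in different surroundings: 1662 of the 1901 2 h-only regions (87.4%) were inside loci that had peaks in all 6 lists, against 899 of the 2637 24 h-only regions (34.1%), while 1405 (53.3%) of the 24 h-only regions were in loci with peaks only at 24 h. Of all peaks, 92.3% to 94.1% per 2 h list and 82.4% to 84.4% per 24 h list lay in loci with peaks in all 6 lists. The share of the 2 h-only regions was thus not above that of 2 h peaks in general. The lower share of the 24 h-only regions is not separate from the locus counts, because no region inside a 24 h-only locus can have a 2 h peak. No single region was tested, because presence in 3 of 3 against 0 of 3 lists cannot give an exact two-sided p below 0.1. Leaving out 1 list loosened the requirement and raised the counts to between 3026 and 4718 at 24 h and between 3095 and 3558 at 2 h. With 1 list left out, the time with fewer lists had the looser requirement, so these counts do not compare the times.

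**Figure D3:**
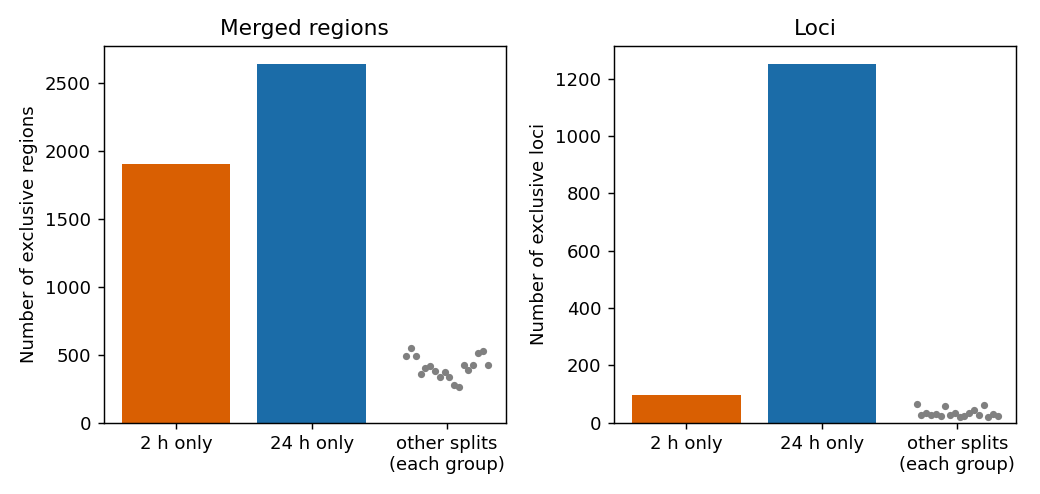
Bars give the number of merged regions (left) and of loci (right) with a peak in all 3 lists of 1 time and in none of the other, and grey points give the same count for each group of 3 lists in the other 9 splits of the 6 lists. The loci number 96 at 2 h and 1252 at 24 h, and the highest grey point for loci is 64.

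The regions named here were the 5 per time with the highest smallest score percentile. At 24 h, 16 regions, and at 2 h, 13 regions, tied with an infinite score in all 3 lists, and the first 5 by sequence name and position were taken. At 24 h these were NC_049714.1 from 8705748 to 8705772 (25 bases, minus strand), NC_049715.1 from 11588850 to 11589099 (250 bases, minus strand), NC_049717.1 from 8374786 to 8374960 (175 bases, plus strand), and, on the plus strand of NC_049719.1, 2817413 to 2817862 (450 bases) and 2853766 to 2854065 (300 bases). The last 3 of these lay in loci with peaks only at 24 h, and the first and second in loci with peaks in all 6 lists. At 2 h the regions were NC_049710.1 from 12706018 to 12706067 (50 bases, minus strand), NC_049711.1 from 11802044 to 11802068 (25 bases, minus strand), NC_049715.1 from 3795703 to 3795777 (75 bases, plus strand), NC_049718.1 from 3764156 to 3780589 (16434 bases, plus strand) and NC_049718.1 from 13678874 to 13678998 (125 bases, minus strand). All 5 of the 2 h regions lay in loci with peaks in all 6 lists. Whether these positions are exonic or intronic is not analysed here.

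Along the genomic span of loci, m6A peaks gathered towards the 3' end at both times. Each of 7655 loci with a peak in all 6 lists and a span over 1000 bases was divided into 10 equal parts of genomic length. The parts ran in the direction of the deposited strand and can include introns. The last part held 25.1% ± 0.546 of peaks (SD, n = 6 lists), the first part 12.7% ± 0.233 (SD, n = 6), and each of parts 4 to 7 held 6.90% on average. The last part exceeded the first by 12.4 percentage points (exact two-sided sign-flip p = 0.03125, adjusted p = 0.0469 over 3 comparisons, higher in 6 of 6 lists). Peaks in the last part were also the stronger ones by the deposited score, with a median within-list percentile of 60.6 ± 2.52 (SD, n = 6) against 49.3 ± 0.515 (SD, n = 6) in the first part (exact two-sided sign-flip p = 0.03125, adjusted p = 0.0469, 6 of 6 lists). In this percentile the first part stood 0.886 ± 1.58 (SD, n = 6) above parts 4 to 7, higher in 5 of 6 lists (exact two-sided sign-flip p = 0.219). The share in the last part was 25.4% ± 0.491 (SD, n = 3) at 2 h and 24.7% ± 0.442 (SD, n = 3) at 24 h, a difference within the range of the lists (exact two-sided permutation p = 0.2). Locus ends are themselves set by peaks, which raises the share in both outer parts, and with a joining distance of 500 bases the last part exceeded the first by 7.76 percentage points (exact two-sided sign-flip p = 0.03125, n = 6). This comparison was chosen after the data were seen, in place of the planned position in transcripts. The density of exons along loci was not known, so the shares are not adjusted for it. The RNA had been enriched on oligo(dT) beads and the input was not used. Neither the shares nor the scores are therefore adjusted for read coverage along transcripts.

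**Figure D4:**
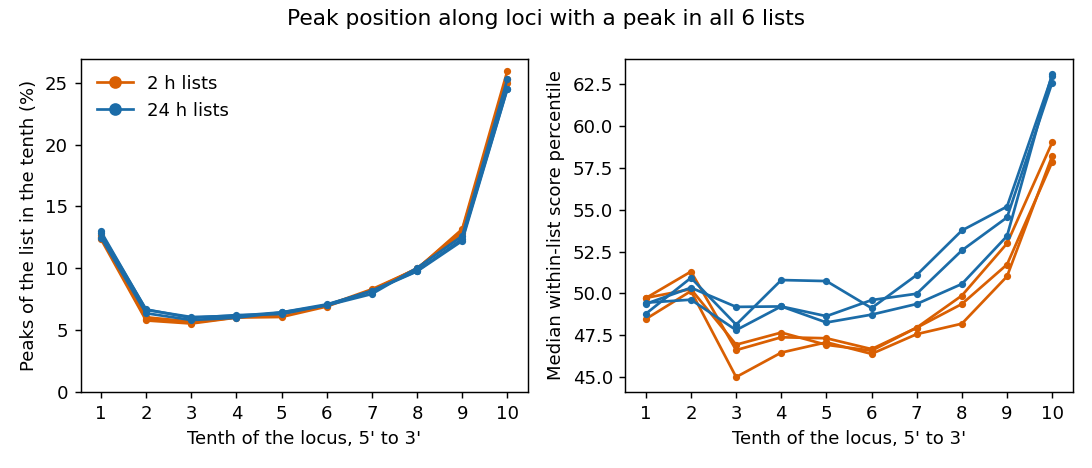
Each line is 1 of the 6 peak lists, coloured by time; the horizontal axis gives 10 equal parts of the locus from 5' to 3', and the vertical axes give the percent of the list's peaks in that part and the median within-list percentile of the deposited score. The last part holds 25.1% of peaks on average and has a median percentile of 60.6.

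The mitochondrial transcripts carried m6A peaks at both times. All 13 mitochondrial coding genes had a peak in all 6 lists, and none was specific to a time. Peaks covered 80.4% ± 2.1 (SD, n = 3) of the joint coding length at 2 h and 75.8% ± 1.06 (SD, n = 3) at 24 h, with every 24 h list below every 2 h list (exact two-sided permutation p = 0.1). Mean coverage was lower at 24 h in 10 of the 13 genes and higher in none. *ND3* and *ND5*, which encode subunits of respiratory complex I, had 3 lists of 24 h below 3 lists of 2 h: for *ND3* coverage was 75.8% ± 4.10 at 2 h and 61.6% ± 4.10 at 24 h (SD, n = 3 each, exact two-sided permutation p = 0.1), and for *ND5* 81.1% ± 2.19 and 72.9% ± 2.42 (SD, n = 3 each, exact two-sided permutation p = 0.1). Neither passed adjustment over the 13 genes, with a smallest adjusted p of 0.65, and chance alone gives such separation in 10% of genes. For *ND3* the lowest 2 h list (71.0%) and the highest 24 h list (63.9%) were only a single 25-base step apart. Among the subunits of cytochrome c oxidase, *COX1* was covered to 49.0% ± 5.89 at 2 h and 39.7% ± 3.40 at 24 h (SD, n = 3 each, exact two-sided permutation p = 0.2), *COX3* to 85.2% ± 3.66 and 77.8% ± 5.49 (SD, n = 3 each, exact two-sided permutation p = 0.3), and *COX2* to 99.0% in all 6 lists. The ATP synthase gene *ATP8* was covered to 84.6% in all 6 lists, and *ATP6* to 88.9% at 2 h and 87.7% ± 2.13 at 24 h. *CYTB*, the cytochrome b gene of complex III, was covered to 71.9% ± 2.18 and 69.0% ± 1.26 (SD, n = 3 each, exact two-sided permutation p = 0.3). For the remaining complex I genes the 2 h and 24 h means were 91.7% and 90.0% (*ND2*), 94.0% and 94.0% (*ND4*), 98.2% and 96.3% (*ND4L*), 92.6% and 91.0% (*ND6*), and 74.3% and 69.2% (*ND1*). In 8 genes a peak had an infinite score in all 6 lists, *COX1*, *COX2*, *COX3*, *ATP6*, *ATP8*, *ND5*, *CYTB* and *ND1*. *ATP8* and *ATP6* overlap, so a peak over their junction counts for both.

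**Figure D5:**
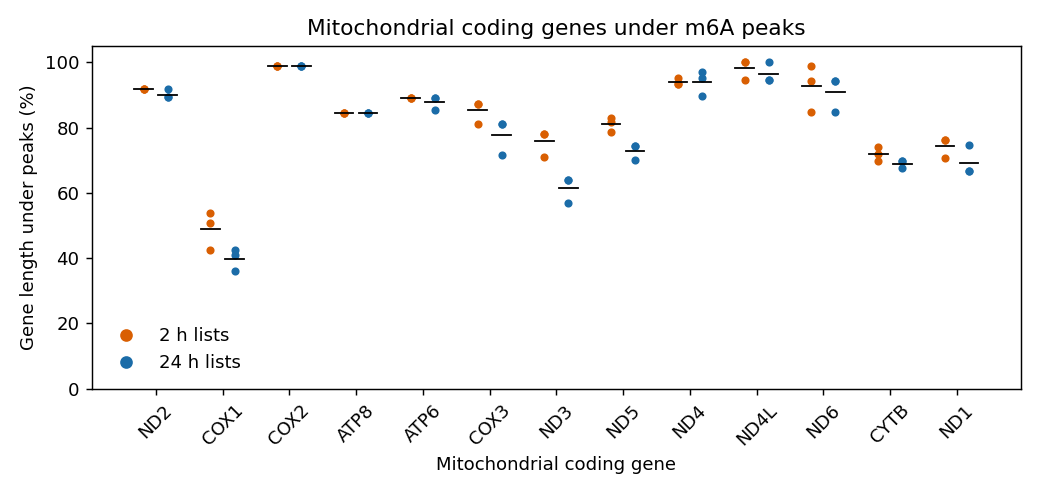
Points give the percent of each mitochondrial coding gene's length under m6A peaks (vertical axis) in each of the 3 lists of 2 h and of 24 h, with short lines at the means; genes are on the horizontal axis. *COX1* has the lowest means, 49.0% and 39.7%.

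The 24 h-only loci were unevenly spread over the genome. Of the 24 h-only loci and the loci with peaks in all 6 lists together, 12.3% were 24 h-only across the 31 sequences with at least 100 such loci. The share was highest on NC_049736.1, at 23.5% of 153 loci (exact 95% binomial interval 17.1% to 31.1%), and NC_049739.1, at 20.3% of 138 (13.9% to 28.0%), and lowest on NC_049740.1, at 4.26% of 188 (1.85% to 8.21%), and NC_049738.1, at 6.77% of 133 (3.14% to 12.5%). The spread over sequences was larger than in 10000 shuffles of the loci (chi-square 124.2, permutation p = 0.0001, one-sided, the smallest these shuffles can give). In the stronger 50% of each list by score the chi-square was 46.95 (permutation p = 0.005, one-sided, 10000 shuffles). Neighbouring loci are not independent, which makes these p-values too small.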

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

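The settings on span, strand, joining distance and 75-base peaks were chosen after the data were seen, as were the results on loci and positions along loci. Without peaks of 75 bases the difference in number of peaks, 4018, turned to -100, and the excess of 24 h-only over 2 h-only regions (2637 against 1901) turned to 1687 against 1857. With spans of at most 1000 bases the difference in covered length fell from 6.55 Mb to 0.0878 Mb. In the stronger 50% of each list the difference in covered length was 3.84 Mb, that in 75-base peaks fell from 4118 to 1189, and the chi-square of 24 h-only loci over sequences from 124.2 to 46.95. The excess of within-time overlap, 0.118, was 0.0751 to 0.0834 without 1 of the 2 h lists and 0.144 to 0.168 without 1 of the 24 h lists. It was 0.0766 with spans of at most 1000 bases, 0.0712 as a share of peaks overlapped, and 0.0655 as that share without 75-base peaks. With spans of at most 1000 bases and as the share of all peaks, it came from the 2 h pairs alone.

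Presence in at least 2 of 3 lists gave 8551 regions only at 24 h and 6057 only at 2 h, and 2119 and 267 loci. Leaving out 1 list at a time gave 3026 to 4718 regions at 24 h and 3095 to 3558 at 2 h, and 1337 to 1708 and 145 to 218 loci, because fewer lists had to meet the requirement. A joining distance of 10000 bases gave 816 and 24 loci, and one of 500 bases gave 341 loci at 2 h. The share of 2 h-only regions in loci of all lists was 76.7% in the stronger 50% of each list, 85.0% at equal list length, 84.8% with spans of at most 1000 bases, 90.9% with strand ignored, and 67.9% and 95.7% with distances of 500 and 10000 bases. For 24 h-only regions it was 28.4% in the stronger 50%, 31.6% at equal length, 42.6% with strand ignored, and 20.5% and 50.5% with the 2 distances. Without 1 list these shares lay between 86.8% and 90.7% at 2 h and between 42.4% and 44.6% at 24 h. The 2 h share was higher in each, and the causes of the shifts were not tested.

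The excess of the last over the first of the 10 parts of loci was 11.7 to 12.0 percentage points without 1 list, where 5 lists cannot give an exact p below 0.0625. It was 7.76 with a joining distance of 500 bases, 15.5 with 10000 bases and 9.14 with spans of at most 1000 bases, against 12.4. The difference for *ND6* ranged from -5.49 to 1.57 and turned positive without the third 2 h list or the second 24 h list. Of the named regions and loci, 175 of 180 values stayed exclusive, and the other 5 were the 2 h-only loci in the stronger 50% of each list. Leaving out a list cannot undo exclusivity, so most of these values were fixed in advance and do not measure stability. With a replicate block the differences of 4018 peaks, 6.55 Mb and 4118 peaks of 75 bases had an exact sign-flip p = 0.25, the smallest 3 pairs can give. Whether the numbers pair the samples was not settled, and all same-number correlations were under 0.1. They were 0.0013 to 0.0077 over regions, where 6 of the 6 lists correlated best with their own number. Over loci they were -0.0057 to 0.0093, where 3 of the 6 did. The alternatives for position in transcripts, motif and gene lists were not run. Depth is unknown, which limits what an absent peak says.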

Other observations

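The tests of depth, of a single aberrant list, of 75-base peaks in 24 h-only loci, of overlap counted by peaks and of other splits of the lists were chosen after the results were seen.

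Stretches of the genome held several 24 h-only loci in a row, with no locus shared by all lists or specific to 2 h between them. The longest run was 11 loci on NC_049722.1 from 5303988 to 6096819, all on the minus strand. A run of 10 on NC_049717.1 from 6995794 to 7109976 had 9 loci on the plus strand. Runs of 7 lay on NC_049727.1 from 1889739 to 2059462 and on NC_049730.1 from 11452684 to 11606339, the latter with 3 plus-strand and 4 minus-strand loci. Neighbouring 24 h-only loci on the same strand formed 389 pairs, 4.62 times the mean of 10000 shuffles within sequences (permutation p = 0.0001, one-sided, the smallest these can give). On opposite strands there were 91 pairs, 1.09 times the shuffled mean (permutation p = 0.2, one-sided). The excess of same-strand neighbours may therefore come from long genes broken into several loci by introns, though same-strand clusters of related genes stay open, since no annotation was used.

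More loci had peaks only at 24 h (1252) than only at 2 h (96). The longer 24 h lists do not account for all of it, because at equal list length the ratio was 8.15, against 13.04 in the whole lists. In the stronger 50% of each list the ratio was 6.89, which cannot exclude weak calls. The median 24 h-only locus had its strongest peak at percentile 34.7 in its lowest list, so under 50% of the 1252 loci could pass in every list. Yet 972 loci were 24 h-only after the cut, so the cut itself created exclusive loci. A lower depth of the 2 h libraries would leave fewer 2 h peaks in shared loci too, but the 24 h lists held fewer there, by a mean difference of -1873 peaks (exact two-sided permutation p = 0.2), which overlaps in range and cannot exclude it. The number of splits as large as the real one was 1 of 10 for loci (1348 exclusive loci, highest other 85) and 1 of 10 for regions (4538, highest other 891), and 10 splits are too few for a share under 0.05. Another explanation, transcripts absent from the 2 h embryo and made by 24 h, stays open and was not tested because the input samples were not used here.

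The 24 h lists overlapped each other less than the 2 h lists did. Leaving out the weaker calls did not narrow the gap of 0.153 in Jaccard index, which was 0.155 in the stronger 50% of each list. Without 75-base peaks it was 0.148, which decides nothing because they cover at most 3.24% of a list's length, but counted by peaks the gap in the share overlapped was still 0.125 without them. A single aberrant list would leave 1 high 24 h pair, but the highest 24 h pair was at 0.383 and the lowest 2 h pair at 0.526. Of the 75-base peaks that the 24 h lists held in excess, 46.6% (44.3% to 47.4% by list) lay in regions of 1 list, where they numbered 628 per list at 2 h and 2546 at 24 h (7.39% and 20.2% of 75-base peaks), so such calls are a large part of the excess. Whether they are most of it is not settled, because a peak that touched any span of another list, also a long one, counted as shared. The share in regions of 1 list was also higher at 24 h for peaks of 25 bases (23.6% and 29.9%), 50 bases (11.7% and 17.7%) and 100 bases (1.25% and 4.10%). A rise in unshared calls was thus not particular to 75-base peaks. By locus, 46.8% of the excess lay in loci of all 6 lists and 27.6% (23.4% to 35.0%) in 24 h-only loci. A more varied mixture of stages or tissues among 24 h embryos could also lower the overlap, and so could a difference in depth, and neither was tested.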
